A study of Drosophila melanogaster with 8 samples.

How the data were processed

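Total RNA of last-instar wing discs from Oregon R and from homozygous BEAF-32 mutant larvae of matched age was reverse transcribed from oligo-dT, labelled with Cy3 and hybridised to NimbleGen arrays, per the labels' protocols. There were 4 arrays per genotype. The series' design text states 2 biological and 2 experimental replicates, and titles carry a pair of numbers whose meaning the labels do not give. The deposited value table holds 1 log2 value per transcript and array. RMA and Partek are named in the submitters' processing notes, without versions. RMA corrects background, equalises the distributions of arrays and summarises probes. Array medians were close, at 9.364 to 9.433, but the distributions were not identical. Wildtype arrays 1_1 and 1_2 were wider than the others. Their lower quartiles were 7.946 and 7.951, against 8.067 to 8.159 on the other arrays. Their upper quartiles were 11.312 and 11.292, against 11.127 to 11.181. Equalising distributions can hide a shift that most genes share. Genome build, probe design and probe-level signals are not given in the sources used here, so signal over background could not be set per array and only the floor of the values near 6.833 marks it. The number of arrays limits the precision.

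The authors' deposited table lists transcripts changed at least 1.5-fold, with a ratio of wildtype over mutant, a fold change, p-values, F statistics as scores and sums of squares. Signs here are mutant minus wildtype, so they oppose that ratio. Its F statistics correspond to 5 and 6 degrees of freedom, which implies 6 groups over 12 arrays, more than the 8 arrays used here. Its p-values are therefore not from the model used here. The value table names transcripts only by identifier, and gene names were taken from the authors' deposited table. Of its 3850 genes, 2541 matched a RefSeq gene table (assembly Release 6 plus ISO1 MT) by symbol and 1079 by synonym, and 230 kept the name in the file. Genes are counted by the identifier in the file, and 85 identifiers share 41 current symbols, so that some genes are counted more than once. The other 12258 transcripts stay unnamed. A list member that is not listed can be unnamed, absent from the array, or changed by less than 1.5-fold, and set tests compare a list with other named genes only. The RefSeq table served for names, chromosome arms and the order of neighbours.

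The arrays of a genotype that share the first number were averaged, which gave 2 values per genotype. This was fixed before the data were examined, as were the gene lists, the tests and the rule for named genes. Each named gene was represented by its transcript with the highest mean, and each unnamed transcript by itself. limma 3.58.1 in R 4.3.3 (lmFit, eBayes) tested mutant minus wildtype with genotype as the only term, with Benjamini-Hochberg adjustment and a threshold of 0.05. The residual degrees of freedom were 2 and the prior degrees of freedom 2.21. Every adjusted p for a gene is from limma. "Rose" and "fell" mean that a gene passed. The 32 lists were fixed before the data were examined. The 24 lists with at least 5 listed genes were tested with limma's camera at a preset correlation of 0.01, adjusted over lists. They were tested again with an estimated correlation, with which 0 of the 6 called lists held. With 2 residual degrees of freedom that second test had little power to pass any list. Its lowest adjusted p was 0.66, so failing it does not count against a list. "Adjusted over the list alone" means Benjamini-Hochberg over the listed members of that list, which were selected by a change of at least 1.5-fold, so that these counts are not independent evidence. They were also taken with every fixed member in the family and unlisted members at a p of 1, a choice made after seeing the data. Python 3.11.15 with scipy 1.17.1 gave Fisher's exact tests, and matplotlib 3.10.9 the figures.

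Named genes are BEAF-32, then the 12 largest rises and 12 largest falls among genes that passed, had a symbol that is not only a CG or CR number, lay above the median level in the higher genotype and had no overlap between arrays. For each list up to 4 passing members with the smallest adjusted p were named, or 2 by p where none passed. Further genes are named where a small count or a singled-out feature called for it, and these were chosen after their values were seen.

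The limma step was tested on simulated data for BEAF-32 mutant against wildtype with 2 averaged replicates each. Of 100 transcripts changed by 1 on the log2 scale 28% were recovered, and of 100 changed by 2, 97%. There were 132 calls, of which 7 were false. The simulated transcripts were independent, had equal spread in both genotypes, and no others of the 16637 were changed. In the data the wildtype replicates differed by a median of 0.258 and the mutant replicates by 0.122, and many more features differed between genotypes. These rates therefore need not hold for the data.

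The alternatives covered which number marks the replicate, all 8 arrays with and without random or fixed blocks, further scaling, a filter on the lowest 25% of features, eBayes with trend and robust set, the mean of a gene's transcripts, other thresholds, and leaving out each array and each averaged replicate. Chromosome arms were planned as called genes against all tested genes; since uncalled features are largely unnamed, the direction of listed genes was tested instead. Promoter motif and divergent gene pair tests were planned and not run, because a genome sequence was not used here and uncalled genes are unnamed.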

Results

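RNA from wing imaginal discs, the larval epithelial sacs that form the adult wing and the back of the thorax, was measured on 8 one-colour expression arrays. The larvae were last-instar Drosophila melanogaster, either wildtype Oregon R or homozygous mutant for BEAF-32, which encodes a chromatin-binding boundary (insulator) protein. Each genotype had 4 arrays, and the deposited value table held a log2 value for 16637 transcripts on every array. Array medians lay between 9.364 and 9.433, and the lowest values between 6.833 and 6.896. Arrays of 1 genotype that shared the first number of their title correlated at 0.9977 to 0.9986 across transcripts, against 0.9662 to 0.97 for wildtype arrays with different first numbers and 0.9852 to 0.987 for mutant arrays. Such arrays were averaged, which left 2 replicate values per genotype, and all means below are ± SD with n = 2. The labels do not say that replicates came from separate animals or dissections, so the p-values measure the spread between these samples, which may in part be technical. Transcripts across arrays of different genotypes correlated at 0.9023 to 0.9327.

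The comparison asked which genes differ in expression between wing discs with and without BEAF-32. The BEAF-32 transcript itself (gene FBgn0015602) fell from 10.61 ± 0.57 in wildtype to 8.44 ± 0.05 in the mutant, a log2 change of -2.17 (SE 0.3, 4.51-fold, adjusted p = 0.034). All 4 mutant arrays lay below all 4 wildtype arrays. Wildtype array 1_2 read 11.94 and the next highest wildtype array 10.28. Without wildtype replicate 1_2 the log2 change was -1.71 with an adjusted p of 0.013, and without wildtype replicate 1_1 it was -2.64 with an adjusted p of 0.085. The adjusted p was 0.19 without mutant replicate 1, 0.19 without mutant replicate 2 and 0.17 with all 8 arrays and the first number as a random block. Whether the probes of this transcript lie in the mutated part of the gene is not given in the sources used here.

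Among the genes that rose most in the mutant was Ilp8, an insulin-like peptide that damaged or overgrown discs release to delay metamorphosis, at 7.85 ± 0.22 in wildtype and 13.57 ± 0.01 in the mutant (log2 change 5.72, SE 0.15, adjusted p = 0.0033). Ldh, lactate dehydrogenase, rose by 5.27 on the log2 scale (adjusted p = 0.0036), and the cuticle protein gene Cpr47Eb by 4.67 (adjusted p = 0.0065). The eye pigment transporter gene w (white) went from 9.89 ± 0.05 to 14.35 ± 0.02. The design holds a single mutant stock, so other differences between it and Oregon R cannot be told apart from loss of BEAF-32. This holds for w as for every other gene here. The other largest rises were those of Arc1 at 4.23, Reepl1 at 4.05, Dgp-1 at 3.65, yellow-b at 3.61, nAChRbeta3 at 3.51 (1.57 for its other listed transcript), bero at 3.49, and ftz-f1 and fru at 3.40 each (2.76 to 3.54 over 5 listed transcripts of fru). Among the 12 largest falls, 8 were of the salivary gland: Sgs5 (-7.50), Sgs7 (-7.05), Sgs8 (-6.0), Sgs5bis (-5.91), Sgs1 (-5.71) and Sgs3 (-4.68), which are glue protein genes or close relatives, with Eig71Ee (-6.35) and ng3 (-4.91). Fbp1, a fat body receptor for storage proteins, fell by 6.21 on the log2 scale, the odorant-binding protein gene Obp99b fell by 6.04, and the ecdysone-inducible ImpE2 fell by 4.70. The remaining gene was l(2)gl, the tumour suppressor lethal giant larvae that sets the basolateral side of epithelial cells. It fell from 12.99 ± 0.21 to 6.90 ± 0.01 (68.2-fold, adjusted p = 0.0033), and on each mutant array it lay within 0.04 of the lowest value of that array.

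**Figure D1:**
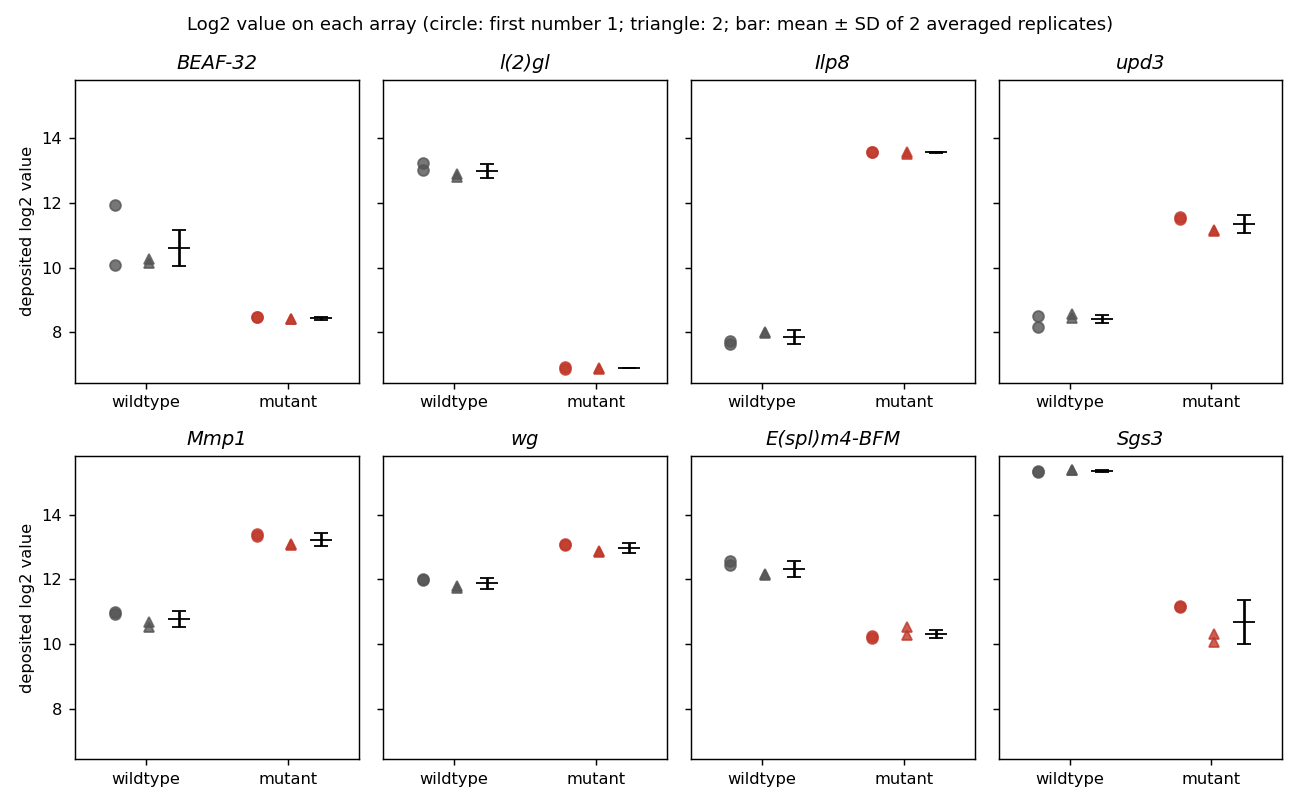
Deposited log2 value (vertical axis) of 8 genes on each of the 8 arrays, wildtype in grey and BEAF-32 mutant in red; circles are arrays whose first number is 1, triangles those whose first number is 2, and each bar is the mean ± SD of the 2 averaged replicates. The mutant arrays of l(2)gl sit near 6.90 and those of Ilp8 near 13.57, and 1 wildtype array of BEAF-32 stands at 11.94.

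Over 16108 tested features, of which 3850 are named genes and 12258 are transcripts without a name here, 450 genes rose and 719 fell in the mutant (limma, adjusted p under 0.05). All 1169 are named and changed at least 1.59-fold, with a median of 2.53-fold, and 281 changed over 4-fold. At an unadjusted p under 0.05 there were 4394. Without mutant replicate 1 limma called 0 genes (2022 at an unadjusted p under 0.05) and without mutant replicate 2 it called 2 higher and 14 lower, since the spread then came from the wildtype pair alone; the median size of the 1169 changes was 1.36 on the log2 scale in both fits, against 1.34. Without wildtype replicate 2 it called 2476 higher and 2380 lower. With arrays that share the second number averaged in place of the first, 6893 features were higher and 5472 lower, unnamed transcripts included. With the 8 arrays as separate samples the counts were 3935 and 3691, and with the first number as a random block 1446 and 1881.

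Of the 20 genes fixed for the JNK pathway and its wound and tumour targets, 9 were named in the authors' deposited table; 7 of these rose, 0 fell and 2 did not pass (rpr and Mmp2), and adjusted over the list alone 8 higher and 1 lower passed. Members had to change at least 1.5-fold to be listed, so counts adjusted over the list alone rest on genes selected by their change and are not independent evidence. Summed over lists they come to 200 of 245 listed members, to 142 with all fixed members in the family (unlisted ones at a p of 1, a choice made after seeing the data), and to 94 over all genes. Beside Ilp8 the risers included Mmp1, a matrix metalloproteinase (log2 change 2.45, adjusted p = 0.013), puc, the phosphatase that feeds back on JNK (1.18, adjusted p = 0.019), and Ets21C, a transcription factor (3.30, adjusted p = 0.028). The set test gave an adjusted p of 0.0037, and with an estimated correlation an adjusted p = 0.66. Here and below, the test with an estimated correlation had little power for any list, given 2 residual degrees of freedom. All 6 listed genes of the JAK/STAT pathway were higher and 3 of them rose: the secreted ligands upd3 (2.93, adjusted p = 0.0099) and upd2 (2.37, adjusted p = 0.021), and the target chinmo (3.25, adjusted p = 0.027, with its other listed transcript at 4.22). Adjusted over the list alone 5 higher and 0 lower passed. The JAK/STAT set test gave an adjusted p of 0.017 (0.059 without wildtype replicate 2), and with an estimated correlation an adjusted p = 0.66. Haemocyte markers, given here because blood cells attach to discs, were higher in the same samples, with 5 of 9 rising. In these samples l(2)gl lay near the floor of every mutant array. Changes that follow its low level and changes that follow loss of BEAF-32 cannot be told apart with this design.

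Of 8 listed genes for apicobasal polarity and junctions, 0 rose, 2 fell and 6 did not pass; adjusted over the list alone 4 higher and 3 lower passed. The genes that fell were l(2)gl and the junction gene p120ctn (log2 change -1.26, adjusted p = 0.028). In the Wingless list, 1 of 8 listed genes rose and 1 fell: the ligand gene wg went from 11.89 ± 0.17 to 12.97 ± 0.16 (adjusted p = 0.037), and the co-receptor gene arr from 12.75 ± 0.11 to 11.44 ± 0.18 (adjusted p = 0.026). Adjusted over the list alone 4 higher and 2 lower Wingless genes passed (2 and 2 with all 26 members in the family). The planar cell polarity list had 9 listed identifiers for 8 genes, since mwh stood under a pair of identifiers (0.86 and 0.63), and only lft fell (-1.22, adjusted p = 0.023), and adjusted over the list alone 2 higher and 3 lower passed. In the Hippo and Yorkie-target list 4 of 10 rose, namely kibra (2.03, adjusted p = 0.019), Myc (1.13), Tao (0.98) and vn (0.89), and mats, a co-activator of the Hippo pathway kinase, fell by 1.01; adjusted over the list alone 7 higher and 2 lower passed. None of these lists passed as a set with camera, with adjusted p of 0.99 for apicobasal polarity, 0.61 for Wingless, 0.96 for planar cell polarity and 0.17 for Hippo.

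All 6 listed genes of the Notch list were lower in the mutant, and 3 fell: E(spl)m4-BFM (-2.02, adjusted p = 0.016), E(spl)m7-HLH (-1.31, adjusted p = 0.018) and E(spl)malpha-BFM (-1.08, adjusted p = 0.048), all genes that Notch activates. Adjusted over the list alone 6 passed, all lower. The set test gave an adjusted p of 0.052, and fry an adjusted p of 0.022. Camera and fry were both run on listed members, selected by a change of at least 1.5-fold, so passes with either are not independent evidence. Of 18 listed wing disc patterning regulators 2 rose (vn and brk) and 5 fell; adjusted over the list alone 2 higher and 11 lower passed, and as a set the adjusted p was 0.086. The falls were in al (-2.80, adjusted p = 0.026), bs (-1.12), ara (-1.27), mirr (-0.98) and inv (-1.15). Among 6 listed EGFR pathway genes only the ligand gene vn rose (adjusted p = 0.037). Adjusted over the list alone 4 higher and 1 lower passed (1 and 0 with all 19 members in the family), with a set adjusted p of 0.19.

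The ecdysone cascade and moulting list was split. Of 16 listed genes 4 rose and 6 fell, and adjusted over the list alone 5 higher and 9 lower passed. ImpE1 (-3.15), ImpE2, ImpE3 (-3.66, adjusted p = 0.0056), Eip78C (-3.19, adjusted p = 0.0089), Hr3 (-2.55) and Hr4 (-2.08) fell, and most of these are induced by the hormone before pupariation. The genes that rose were ftz-f1, Ldh, ImpL2 (3.21) and ken (2.07). As a set the list had an adjusted p of 0.45 with camera and 0.027 with fry. The salivary gland and fat body markers described below were lower in the same mutant samples.

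Of 90 genes in the oxidative phosphorylation list 31 were named in the authors' deposited table, all 31 below wildtype, and 6 fell, among them UQCR-11 (-1.05, adjusted p = 0.025), ATPsynG (-1.40, adjusted p = 0.026), COX7A (-1.13, adjusted p = 0.027) and ND-MLRQ (-1.20, adjusted p = 0.029). Adjusted over the list alone 24 passed, all lower, and 10 with all 90 members in the family. The set test gave an adjusted p of 0.00021, and with an estimated correlation an adjusted p = 0.67. Tested with fry, which asks whether the genes of a list move one way on balance, the list did not pass (adjusted p = 0.084). Its median log2 change was -1.12 against wildtype replicate 1 alone and -0.69 against wildtype replicate 2 alone. In the same samples 10 of 10 listed fat body markers, 12 of 12 salivary gland markers and 5 of 6 muscle markers were lower. Only 3 of 86 cytoplasmic ribosomal protein genes were listed and 0 of these passed, with RpS19b at -0.59 (adjusted p = 0.086) and RpL15 at -0.86 (adjusted p = 0.098); adjusted over the list alone 2 passed, both lower (0 with all 86 members in the family). In the cell cycle and replication list, 1 of 7 listed genes rose, the mitotic phosphatase gene stg (1.14, adjusted p = 0.04), and 2 fell, Cdk4 (-1.03) and E2f2 (-0.98). Adjusted over the list alone 1 higher and 5 lower passed (1 and 2 with all 38 members in the family), with a set adjusted p of 0.21. Of 5 listed apoptosis genes p53 rose (0.89, adjusted p = 0.036, with its other listed transcript at 1.81) and the apoptosome gene Dark fell (-1.63, adjusted p = 0.012); adjusted over the list alone 3 higher and 2 lower passed, with a set adjusted p of 0.76, a median of 0.80 and a mean of 0.09.

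In the heat shock list 4 genes were listed; the chaperone genes Hsp27 (-1.06, adjusted p = 0.023) and Hsp23 (-1.06, adjusted p = 0.034) fell and the co-chaperone gene stv rose (0.98), and adjusted over the list alone 1 higher and 3 lower passed. Of 10 detoxification and oxidative stress genes 1 rose, GstE6 (2.55, adjusted p = 0.0086), and 3 fell, Cyp6g1 (-1.81), the catalase gene Cat (-1.34) and Prx5 (-1.11); adjusted over the list alone 4 higher and 5 lower passed, with a set adjusted p of 1, a median of 0.03 and a mean of -0.06. Of 9 antimicrobial and immune genes the peptidoglycan receptor gene PGRP-SA rose (1.82, adjusted p = 0.013) and 8 did not pass. Adjusted over the list alone 4 passed, all higher (1 with all 21 members in the family), with a set adjusted p of 0.086. Among 5 listed insulator and architectural protein genes BEAF-32 alone passed. Adjusted over the list alone 1 higher and 3 lower passed (0 and 1 with all 25 members in the family), with a set adjusted p of 0.71. Of 3 listed Hox genes Scr fell (-1.07, adjusted p = 0.05 after rounding up), and adjusted over the list alone 1 higher and 2 lower passed. The heterochromatin list had 2 listed genes, LBR at -0.77 (adjusted p = 0.071) and HP1c at -0.82 (adjusted p = 0.17), and adjusted over the list alone both passed (0 with all 13 members in the family). The germline list had 3 listed genes with none passing, among them bru1 at -0.78 and piwi at 0.60, and adjusted over the list alone 1 higher and 1 lower passed (0 with all 18 members in the family). None of 18 Polycomb group genes was listed.

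Transcripts of other tissues differed strongly between the genotypes. All 12 listed salivary gland markers fell, with a median log2 change of -4.79; the set test gave an adjusted p of 1.2e-06, and with an estimated correlation an adjusted p = 0.66. Sgs3 went from 15.36 ± 0.03 in wildtype to 10.68 ± 0.68 in the mutant. All 10 listed fat body markers were lower and 4 fell, Fbp1, Fbp2 (-3.35), the storage protein gene Lsp1alpha (-2.92, adjusted p = 0.0096) and Acbp1 (-1.33); adjusted over the list alone 8 passed, all lower. The fat body set had an adjusted p of 0.0036, and with an estimated correlation an adjusted p = 0.67. All 9 listed haemocyte markers were higher and 5 rose, among them the scavenger receptor gene Sr-CI (1.53, adjusted p = 0.014), NimC4 (2.0), the collagen gene vkg (2.33) and the phenoloxidase gene PPO2 (2.69). Adjusted over the list alone 8 haemocyte markers passed, all higher; the set adjusted p was 0.0034, and with an estimated correlation an adjusted p = 0.66. With the 66 listed markers of other tissues and cells left out of the counts, a choice made after seeing the data, 440 genes rose and 697 fell. Leaving out 66 genes can lower the counts by no more than 66, and genes such as Sgs5bis are not on these lists. These counts therefore do not measure how far other tissue affects the calls.

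Of the other marker lists, the tracheal, muscle, neural, gut and leg disc lists did not pass with camera. With fry, run like camera only on members selected by their change, the tracheal (adjusted p = 0.022) and muscle (adjusted p = 0.027) lists passed. The eye disc and male lists had too few listed genes for a set test. Of 6 listed genes of the tracheal list 4 rose and dys fell (-1.70). The risers included the FGF ligand gene bnl (2.94, adjusted p = 0.0089) and the chitin deacetylase genes serp (1.33) and verm (1.31). Since bnl encodes a secreted ligand, its rise does not by itself show more tracheal cells. Adjusted over the list alone 4 higher and 1 lower passed, with a set adjusted p of 0.093. Of 6 muscle and muscle precursor markers 3 fell, the FGF receptor gene htl (-1.47), TpnC73F (-1.78) and wupA (-0.97); adjusted over the list alone 1 higher and 5 lower passed, with a set adjusted p of 0.16. Among 6 neural and glial markers the glial receptor gene moody rose (2.31), adjusted over the list alone this gene passed, and the set adjusted p was 0.61. Of 8 gut markers LysS fell (-0.92); adjusted over the list alone 2 higher and 6 lower passed, with a set adjusted p of 0.22. Of 5 leg disc markers bab2 fell (-2.18); adjusted over the list alone 4 passed, all lower, with a set adjusted p of 0.082. The 4 listed eye disc markers were all lower with none passing, among them toy at -2.27 (adjusted p = 0.095) and sca at -1.49 (adjusted p = 0.098), and adjusted over the list alone 3 passed (0 with all 15 members in the family). Of the male markers only msl-2 was listed, at -0.66 (adjusted p = 0.074), which did not pass. Adjusted over the list alone this gene passed as lower (0 with all 8 members in the family).

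**Figure D2:**
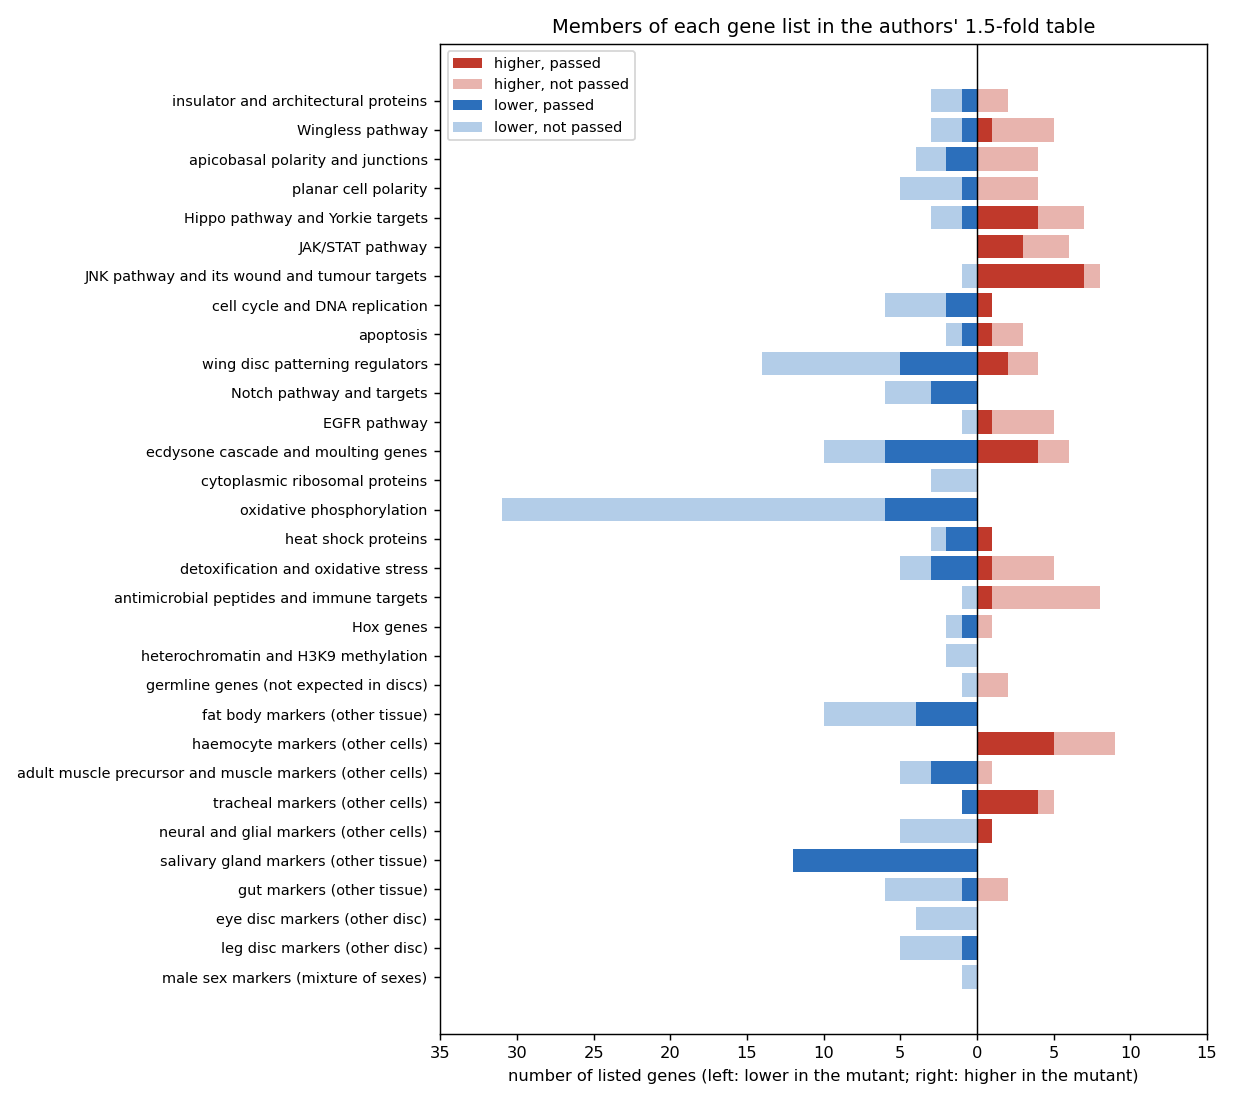
Number of members of each gene list that the authors' deposited table names (horizontal axis, genes lower in the mutant to the left and higher to the right); dark bars passed an adjusted p of 0.05 and light bars did not. All 12 salivary gland markers lie to the left as dark bars, all 31 oxidative phosphorylation genes lie to the left with 6 dark, and 7 JNK genes lie to the right as dark bars.

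Named genes were also set against the chromosome arm they lie on. On the fourth chromosome 28 of 29 listed genes were lower in the mutant (96.6%), against 51% elsewhere (Fisher's exact test, two-sided, adjusted p = 3.8e-07 over 6 arms); 10 of them fell, among them Ephrin (-1.10), Crk (-1.52), Arl4 (-1.22) and Sox102F (-2.08), which were named after their values were seen. The 1 gene that was higher, fuss, was at 0.64 (adjusted p = 0.29). On the X, 40.2% of 562 listed genes were lower against 53.4% elsewhere (adjusted p = 6.7e-08), and on 2L, which carries l(2)gl, 59.3% of 722 against 49.3% (adjusted p = 4e-06). On 2R, which carries BEAF-32, 47.6% of 718 were lower against 52.2% (adjusted p = 0.041). Arms 3L and 3R did not pass, with adjusted p of 0.16 and 1.0. Called genes were a larger share of listed genes on 2L than elsewhere (adjusted p = 0.00012), and other arms did not pass this test, with 0.068 for the X. Genes are not independent replicates, and these tests describe only genes that changed at least 1.5-fold.

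**Figure D3:**
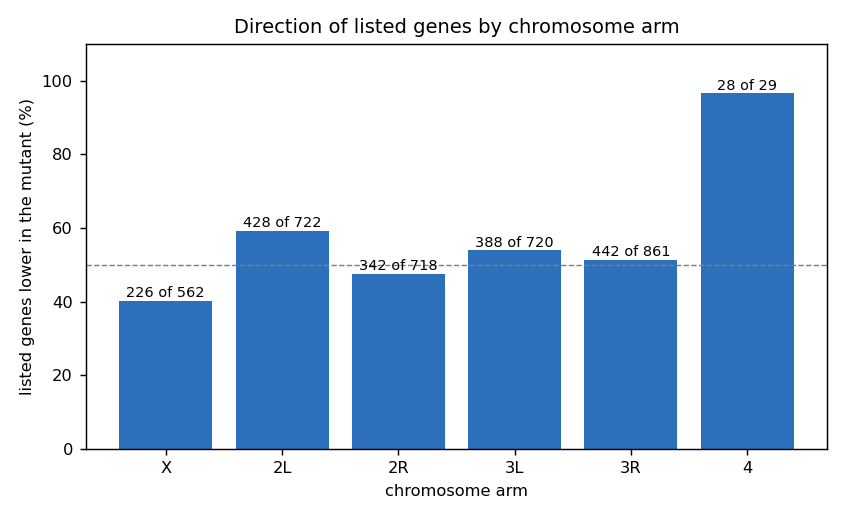
Percent of listed genes that were lower in the mutant (vertical axis) on each chromosome arm (horizontal axis); the number lower and the number listed stand above each bar, and the dashed line marks equal numbers in both directions. The fourth chromosome has 28 of 29 genes lower, and the X has 226 of 562.

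The authors' deposited table of 1.5-fold changes held 4379 transcripts of 3850 genes, with 2195 transcripts higher in the mutant and 2184 lower. All 1169 genes called here were among its genes, which is 30.4% of them, and names in this text come from that table, so this overlap is no independent check. The largest difference between the table's log2 ratio and the difference of the 4-array means was 7.83e-05. There were 13 genes in it that had transcripts in both directions.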

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

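All tests in this part were chosen after the result was seen. For each named gene the 4 arrays of a genotype were searched for a single array far from the others. This flags about 1 in 20 sets of 4 independent values by chance. There were 9 in 184 sets, against 9.2 expected for independent values. The arrays were not independent, since those sharing a first number correlated at 0.9977 to 0.9986, so the count cannot be set against that expectation. BEAF-32 in wildtype array 1_2 stood at 11.94 with the nearest array at 10.28. Mutant array 2_2 of ATPsynG stood at 9.93 (nearest 10.36) and mutant array 2_1 of Sgs1 at 8.12 (nearest 8.42). In wildtype array 2_1 the values were 11.31 for mirr (nearest 11.53), 9.84 for p53 (nearest 9.91) and 13.36 for stv (nearest 13.25). In wildtype array 1_2 Sr-CI stood at 11.67 (nearest 11.58) and verm at 12.98 (nearest 13.14), and in wildtype array 2_2 puc stood at 11.78 (nearest 11.91).

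The gene l(2)gl fell to the floor of the arrays in both mutant replicates. A deletion of the chromosome tip that reaches Cda5, further inward, is argued against, since the lowest mutant replicate of Cda5 lay 0.49 above its highest wildtype replicate on the log2 scale. The neighbour CR11023 read 7.74 to 8.0 on wildtype arrays and 7.14 to 7.25 on mutant arrays, too dim to decide whether a smaller deletion reaches it. A lesion of l(2)gl carried by the mutant stock may account for the level, which was at most 0.04 above the lowest value of a mutant array, and so may loss of BEAF-32, with a smallest difference between a wildtype and a mutant replicate of 5.94. These cannot be told apart, because the design has 1 mutant stock and no rescue.

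Salivary gland transcripts were lower in the mutant, and no explanation tested for this was excluded. Younger glands in the mutant may contribute: sage, ng1, ng2, ng3 and Pig1 had a median log2 change of -2.7 against -5.86 for the 6 listed glue genes, but when these genes are active relative to the glue genes was not measured here. More salivary gland tissue in the wildtype samples would lower the gland's own transcripts by 1 factor, while the largest and smallest falls of the 12 listed markers differed by 5.43 on the log2 scale. Saturation near the top of the arrays, the floor, unequal probe background or expression in discs could also make these falls differ, so age and amount of gland tissue cannot be told apart. Lower activity of these genes without BEAF-32 was not tested.

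Listed genes of the fourth chromosome were lower in 28 of 29 cases. A bias that follows brightness is argued against: 0 of 10000 draws matched on level held as many lower genes (highest 24, median 15; permutation p = 0.0001, the smallest the draws can give). Fewer copies of this chromosome in the mutant could give such a pattern, and this cannot be told apart from other causes. The interquartile range of the log2 changes was 0.7 times that of lower genes elsewhere (95% bootstrap interval 0.41 to 1.69), and genes under 1.5-fold are unnamed, so the sizes are truncated at the same limit in both. Loss of BEAF-32 was not tested as a cause.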

How the results depend on the processing

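No gene called here turned direction under the alternatives that rescale or leave out arrays. Regrouping, blocking and filtering leave the difference of the genotype means unchanged, so direction could not turn there. No called gene list turned under camera or fry. The apoptosis and detoxification lists, which did not pass, were up with camera and down with fry. Counts follow in this order: features higher, lower, changed at least 1.5-fold, and shared with the authors' deposited table. They numbered 6893, 5472, 3851 and 3850 with the second number averaged, and 3935, 3691, 3455 and 3455 with 8 arrays as separate samples. With duplicateCorrelation they numbered 1446, 1881, 2784 and 2784 on genotype and first number, and 7325, 5721, 3850 and 3849 on genotype and second number. With the second number as a block they were 3342, 3359, 3304 and 3304, and with a replicate block of the whole number 4356, 3863, 3614 and 3613. With a replicate block of the first number 736 were higher, 1036 lower and 1772 both at least 1.5-fold and shared; replicate differences correlated at 0.302 between genotypes over only 2 pairs, and the labels give no shared batch, so the numbers were not read as pairing. eBayes with trend and robust gave 748 and 1138. An adjusted p under 0.01 left 37 higher and 65 lower, 102 in all, and 1.5-fold with no test gave 1942, 1910, 3852 and 3850. With the second number averaged more features were higher than lower, against 450 higher and 719 lower with the first. Those features include unnamed transcripts, while the 450 and 719 are all named genes. Treating arrays of 1 replicate as separate samples raises the counts by construction. Grouping by the second number puts arrays of both first numbers into each group. Their difference then no longer adds to the spread, which also raises the counts. The cause of the other moves was not tested. Of the 1169 genes called, 1157 remained with duplicateCorrelation on the first number, 1089 with trend and robust, 981 without wildtype replicate 1 and 14 without mutant replicate 2. Over the alternatives that leave out an array or replicate, counts ranged from 0 to 2476 higher, 0 to 2380 lower, 0 to 4409 at least 1.5-fold and 0 to 3200 shared, where a lone replicate is assumed to vary like the other genotype. BEAF-32 ranged from -2.64 to -1.71 there, and its -2.17 had an adjusted p of 0.17 with duplicateCorrelation on the first number, within a range of 2.9e-05 to 0.19 over all alternatives. Of the named genes and lists that were called, at most 6 lost their call at 0.05 under any alternative that keeps both mutant replicates. Most of the called named genes lost it without a mutant replicate. That leaves the spread to the wildtype pair, whose median difference was 0.258 against 0.122 for the mutant pair. The median size of the 1169 changes was then 1.36 on the log2 scale, against 1.34. With an estimated correlation 0 of the 6 called lists passed, a setting that had little power for any list with 2 residual degrees of freedom. With fry 9 lists passed: oxidative phosphorylation was lost (adjusted p 0.084), and Notch, ecdysone, muscle and tracheal lists were gained. Camera and fry were both run only on members selected by their change, so passes with either are not independent evidence. Added after seeing the data, transcripts counted one by one gave 647 higher and 1012 lower. The promoter motif and divergent pair alternatives were not run. Of the 3 splits of the 4 averaged replicates the real one alone (1 split) gave as many genes, 1169, and the highest other gave 0 (limma; 267 and 17 at an unadjusted p under 0.05); 3 splits are too few for a share under 0.05. Values near the floor understate falls such as that of l(2)gl.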

Other observations

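All tests in this part were chosen after the data were seen. Families of at least 7 named genes that share the letters of their symbol were tested for direction (Fisher's exact test, two-sided, adjusted over 24 families). Proteasome subunits were the exception: symbols starting with Rpn, Rpt, Prosalpha or Prosbeta were pooled by hand into a single family. Subunits of the proteasome, the complex that degrades tagged proteins, were lower in the mutant in 27 of 28 listed genes (adjusted p = 2e-06), and 17 fell. Examples are Rpn10 (-1.43, adjusted p = 0.017), Prosbeta2 (-1.27, adjusted p = 0.022) and Rpt4 (-1.15, adjusted p = 0.028), and the exception was Prosbeta5R2 at 1.36 (adjusted p = 0.065). Heat shock genes were lower in 7 of 7 (adjusted p = 0.015) and 6 fell, among them Hsp67Ba (-3.50) and Hsp60C (-2.91). Mediator subunit genes (MED) were lower in 7 of 7 (adjusted p = 0.015) and 2 fell, MED11 and MED9.

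All 9 listed Mst genes, a family named for male-specific transcripts, were lower (adjusted p = 0.0077) and 4 fell, Mst77F (-2.79, adjusted p = 0.017), Mst77Y-16Psi, Mst33A and Mst87F. The only listed male marker, msl-2, was also lower, at -0.66, and did not pass (limma, adjusted p = 0.074). Whether the share of males differed between the genotypes was not tested. The Jon serine protease genes were lower in 13 of 14 (adjusted p = 0.0053) and 2 fell, Jon25Bii and Jon65Aiv. Jon25Bi and Jon65Aiii are also on the gut marker list, of which 6 of 8 listed members were lower in the same samples, among them epsilonTry (-3.72, adjusted p = 0.053), alphaTry (-2.21, adjusted p = 0.11) and betaTry (-1.31, adjusted p = 0.098). The Jon median log2 change was -3.22 against wildtype replicate 1 alone and -0.58 against wildtype replicate 2 alone, and the wildtype replicates differed by a median of 2.64. All 10 listed histone genes were higher (adjusted p = 0.0077) with a median log2 change of 1.14, and 0 passed with limma. Their median was 1.65 against wildtype replicate 1 alone and 0.69 against wildtype replicate 2 alone, and several are repeat copies of His1, His3 and His4, which the direction test counts as separate genes. Chemoreceptor genes were higher in 13 of 13 (Gr, adjusted p = 0.0019), 15 of 15 (Ir, adjusted p = 0.00072) and 10 of 11 (Or, adjusted p = 0.021), with 0 passing, at median levels of 8.98, 9.46 and 8.76. Their median log2 changes were 1.18, 1.47 and 1.17 against wildtype replicate 1 alone and 0.24, 0.34 and 0.31 against wildtype replicate 2 alone. Of all listed genes 53.8% were higher among the dimmest 25%, against 47.8% among the brightest 25%. Cuticle protein genes of the Cpr family were higher in 16 of 19 (adjusted p = 0.012) and 3 rose, Cpr47Eb, Cpr64Ac (2.94) and Cpr64Aa (1.88), while Cpr12A fell (-1.97). The Cpr median was 1.24 against wildtype replicate 1 alone and 0.48 against wildtype replicate 2 alone. The Lcp family of larval cuticle proteins did not share this direction, with 3 of 7 higher and 4 lower (Fisher's exact test, adjusted p = 0.79).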
